A study of Mus musculus with 24 samples.

How the data were processed

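RAW264.7 mouse macrophage-like cells carrying a construct for Tbc1d23 or for chloramphenicol acetyltransferase (CAT, the control) were left unexposed or exposed to 20 ng/ml LPS for 1, 3 or 5 h. RNA was labelled with Cy3 and hybridised to one-colour Agilent mouse arrays, per the labels. The 24 arrays form 8 groups (line by time) of 3 replicates, which the design text calls biological. The sources used here do not say whether replicates came from separate cultures, so p-values measure the spread between these samples. There was 1 line per construct.

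The deposited scanner files hold the intensity of each spot from Agilent Feature Extraction 10.7.1.1, per the file headers. Its processed signal (background-subtracted, with low values replaced by a surrogate) was the starting point. Values for each probe were also deposited; their log2 scale was found from the values, not from a statement of the authors. They rank almost as the processed signal does (Spearman correlation per array 0.9997 to 0.9999), and every column has the same quartiles (1.671 and 7.728), median (3.873) and maximum (18.397), as quantile normalization of that signal would give, with no centring of genes. The submitters' processing notes name Feature Extraction, RMA and Partek without versions, roles or order. These values were used as an alternative only.

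From 43379 spots of 41174 non-control probes, outlier spots (0.11 to 0.41% per array) were left out and spots of the same probe averaged; no spot was saturated. Values are log2 of the processed signal minus the array's 75th percentile, which was 157 to 363 signal units. Probes well above background on all 3 arrays of at least 1 group were kept (21963), and each gene name was represented by its probe with the highest mean, leaving 15099 gene names, 5069 of them with several probes. Names came from the files. Through RefSeq accessions, 25097 probes matched a current symbol in the GRCm38.p6 gene table, which updated 1613 of the names tested; 12234 of the names are symbols. Probe coordinates are those of the files (mm9).

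On each array 42.1 to 69.6% of probes were well above background and 12.5 to 42.1% of processed signals were surrogates, so the array median lies near background and dim genes carry little information. The number of arrays limits the precision. Where a probe was not well above background in a group, a fold is a lower bound ("at least N-fold"): the brighter group's mean against the mean of, per array, the higher of the lowest signal well above background and the probe's own signal.

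Group means were fitted with limma 3.58.1 (lmFit and eBayes, R 4.3.3, data.table version 1.17.8) with a spread shared by all groups. Contrasts were the Tbc1d23 line minus the CAT line at each time and averaged over times, LPS minus 0 h in each line, and the difference between these LPS responses, Tbc1d23 minus CAT (the interaction). A gene is called at a Benjamini-Hochberg adjusted p under 0.05 within a contrast; the number that also differ at least 2-fold is given beside. Values after ± are standard errors of the limma fit with n = 3 arrays per group unless stated as SD. An exact permutation test of 3 against 3 arrays cannot give a p below 0.1, so p-values rest on limma's model.

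LPS-induced sets hold the genes whose response averaged over both lines had a log2 of at least 2 and was called. That average is independent of the interaction in this balanced design, so the choice favours neither line. The 28 gene lists, the contrasts, the tests, the rule for named genes and most alternatives were chosen before the data were examined. Lists with at least 5 members tested were compared with all other genes by limma's camera (preset correlation 0.01, and again with an estimated correlation), and tested against no change of their own members by fry, with Benjamini-Hochberg adjustment over the lists within a contrast. No gene is in more than 1 list. They cover cytokines, chemokines, immediate early genes, NF-kB targets and feedback, negative regulators of TLR signalling, interferon-stimulated genes, the unfolded protein response, TLR4 pathway components, pattern recognition receptors, inflammatory mediators and enzymes, antigen presentation and costimulation, the Rab GTPase-activating TBC family, trans-Golgi and endosome trafficking, cell cycle, cholesterol synthesis, lipid handling and LXR targets, glycolysis and hypoxia, oxidative phosphorylation, lysosome and autophagy, antioxidant NRF2 targets, heat shock and p53 stress, and markers of macrophages, osteoclasts, dendritic cells, T and NK cells, B cells, granulocytes and erythroid cells, and fibroblasts and epithelium.

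Tbc1d23 is named before all others. Further genes are named by rank among symbols (no accessions, clones or names starting with Gm or LOC or ending in Rik) that are called, are well above background on every array concerned and have groups that do not overlap. These are the 10 highest and 10 lowest line differences averaged over times among genes called in the same direction at all 4 times, the 3 highest and 3 lowest at each time, the 6 highest and 3 lowest LPS responses of the CAT line at each time, and the 5 highest and 5 lowest interaction values at each time (overlap allowed). Of list members, 2 to 4 with the largest change in the contrast, and those with a bound, are examples.

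Each slide held the 4 times of 1 replicate of 1 line, so time and slide position cannot be told apart. The serial numbers of the 6 slides fall into 2 runs: Tbc1d23 replicates 1 and 2, and Tbc1d23 replicate 3 with all CAT slides. Deviations from group means of arrays with the same replicate number, hence the same slide, correlated at 0.52 to 0.83 within the Tbc1d23 line and 0.19 to 0.69 within the CAT line (18 pairs each), so the numbers pair arrays within a line. Between the lines, arrays of the same number and time correlated at -0.41 to -0.07 (12 pairs) and are not paired.

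Alternatives were quantile normalization, median scaling, the deposited values, normexp background correction with offset 50, no filter on dim probes, a filter on all arrays, the mean of probes or every probe, eBayes with trend and robust options, only the groups compared, replicate and slide blocks, a 2-fold minimum, other set minimums and leaving out each array. The slide run as a block, the slides of 1 run alone and a repaired normexp fit were chosen after seeing the data. The code was tested on simulated data with the real means and spreads of 15099 genes, without slide effects. At 0 h it recovered 19.4, 41.8 and 80.3% of line differences of 1.5, 2 and 4-fold, with 5 of 14899 unchanged genes called. At 3 h it recovered 17.9, 62.7 and 78.8% for the CAT response (7 such calls) and 13.4, 46.3 and 69.7% for the interaction (3). Its 74.6, 85.1 and 95.5% (11 calls) for the line difference averaged over times do not hold where arrays share slides. No array was left out.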

Results

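Tbc1d23 belongs to the TBC family, whose members regulate Rab GTPases of membrane traffic, and the comparison asks whether raising it alters the response of macrophages to lipopolysaccharide (LPS), the bacterial ligand of TLR4. RNA of RAW264.7 cells carrying a Tbc1d23 or a CAT construct was measured before LPS (0 h) and after 1, 3 and 5 h, with 3 arrays in each of 8 groups. On the 24 arrays 42.1 to 69.6% of probes were well above background. Replicates of a group correlated at r = 0.967 to 0.993 across genes, and genes are not independent replicates.

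**Figure D1:**
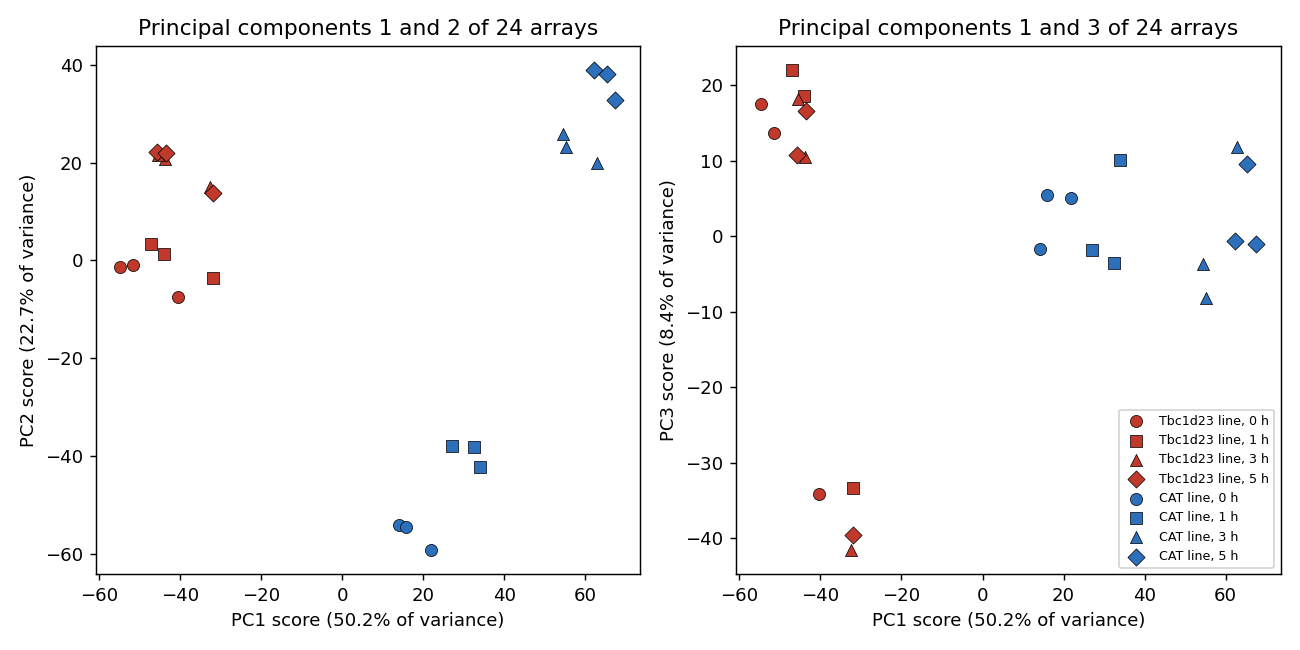
Principal components of the 24 arrays over 11076 genes (PC1 against PC2 and against PC3), each point an array, coloured by line and marked by time; the axes are component scores with the percent of variance each holds. The Tbc1d23 arrays lie between -54.7 and -31.9 on the first axis and the CAT arrays between 14.1 and 67.4.

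The lines lay apart on the axis with 50.2% of the variance, along which CAT arrays also moved with LPS, from 14.1 to 21.9 at 0 h to 62.2 to 67.4 at 5 h. The next axis held 22.7% and ran from -59.3 at 0 h to 39 at 5 h in CAT arrays, against -7.5 to 22.2 in Tbc1d23 arrays. A further axis with 8.4% set Tbc1d23 replicate 3 (-41.6 to -33.3) apart from Tbc1d23 replicates 1 and 2 (10.5 to 22), which lie on slides of another serial run. The run that holds both lines has 1 Tbc1d23 array per time (replicate 3), so in every value given within that run the spread comes from CAT arrays alone, and a deviation of that slide counts as a difference of the Tbc1d23 line. With the slide run as a block the level of the Tbc1d23 line rests on that slide too.

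The Tbc1d23 transcript was not called different between the lines with its brightest probe (A_51_P223575, chromosome 16, 57169122 to 57169181). Its log2 difference (Tbc1d23 minus CAT) was 0.03, -0.16, 0.47 and -0.18 at 0, 1, 3 and 5 h. It averaged 0.04 ± 0.10 over times (limma, adjusted p = 0.745). Such averages take a slide's 4 arrays as independent, so errors and p-values can be too small. The average was 0.40 with the slide run as a block (adjusted p = 0.000556) and within the run that holds both lines. With the mean of probes it was 0.27 (adjusted p = 0.00196). Both values of 0.40 rest on Tbc1d23 replicate 3, at 3.48 to 3.63 against 2.82 to 3.15 in replicates 1 and 2. At 3 h (adjusted p = 0.0681) the probe was called with the slide run as a block (0.83, adjusted p = 5.49e-05). It was called without Tbc1d23 5 h replicate 3 (adjusted p = 0.046) and was 0.87 within the run that holds both lines. With quantile normalization (0.45, adjusted p = 0.0407), the repaired normexp correction (0.44, adjusted p = 0.0182), the mean of probes (0.74, adjusted p = 0.000238) and the slide as a random block (0.47, adjusted p = 0.0419) it was called at 3 h too, and at 0 h with the slide run as a block (0.38, adjusted p = 0.0257). A dimmer probe (A_52_P448220, 57170528 to 57171769) was higher by 0.50 ± 0.09 on average (1.42-fold, adjusted p = 0.000167) and by 1.00 ± 0.19 at 3 h (adjusted p = 0.000396). The remaining probes were well above background on 6 and on 0 arrays. The part of the transcript carried by the construct is not given in the sources used here, and a probe outside it checks nothing.

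Before LPS the Tbc1d23 line had lower transcripts of macrophage genes and of cholesterol synthesis, and members of the unfolded protein response and of the heat shock and p53 stress list were higher (camera adjusted p = 0.109 and 0.108 with an estimated correlation). Among macrophage genes, the chemokine receptor Cx3cr1 was lower by a log2 of -3.80 ± 0.15, the Fc receptor Fcgr2b by -3.26 ± 0.13 and the surface marker Adgre1 by -2.67 ± 0.20. Cholesterol genes included Fdps (-2.41 ± 0.10) and Fdft1 (-2.19 ± 0.17). Trib3 (3.24 ± 0.21) and Ddit3 (1.95 ± 0.19) of the unfolded protein response and Phlda3 (4.60 ± 0.21), Ccng1 (3.17 ± 0.13) and Mdm2 (2.75 ± 0.09) of the heat shock and p53 stress list were higher. Each of these was called by limma with an adjusted p of 1.25e-07 or less.

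At 0 h, 6833 of 15099 genes were called different between the lines, 3789 higher and 3044 lower in the Tbc1d23 line, 2782 of them at least 2-fold. With the slide run as a block 7474 were called, and 5223 within the run that holds both lines (1 Tbc1d23 array, replicate 3, against 3 CAT arrays, with the spread from CAT arrays alone). Quantile normalization turned the split to 3321 higher and 4128 lower, the deposited values to 3255 and 4136, and median scaling to 867 and 3797. The median of all genes moved from 0.09 to -0.07 with quantile normalization and to -0.45 with median scaling, so line differences are relative to that choice. Over 3603 genes with several probes, the line difference at 0 h correlated at r = 0.53 between probes of the same gene, against 0.85 for the CAT response to LPS at 5 h.

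At 1, 3 and 5 h the lines differed in 6906 (3710 higher, 3196 lower), 7703 (4131 and 3572) and 8072 genes (4522 and 3550), of which 2886, 3703 and 4085 at least 2-fold. Averaged over times 10671 genes differed, 5791 higher and 4880 lower, 3484 at least 2-fold. Median scaling gave 1249 higher and 1812 lower at 1 h, 1797 and 2905 at 5 h, and 3194 and 5358 on average. With the slide run as a block the counts at 1, 3 and 5 h and on average were 7410, 8279, 8563 and 10098, and within the run that holds both lines they were 5145, 6355, 6782 and 9893. With the slide as a random block, whose within-slide correlation was 0.568, they were 6912, 7715, 8084 and 8198, and 6713 at 0 h.

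Among the largest lasting differences of genes well above background on every array were those of the Rab GTPase gene Rab15, higher in the Tbc1d23 line, and the scavenger receptor gene Cd36, lower. Of 2634 symbols called in the same direction at all 4 times, 1555 were higher and 1079 lower. The highest averages among such genes were those of Rab15 (7.05 ± 0.12, 133-fold), Phlda3 (5.24 ± 0.10), the nucleotidyl transferase Dntt (5.10 ± 0.21), Acsbg1 (5.07), Dock9 (5.06), Itgb4 (4.89), Slc4a7 (4.75 ± 0.67), Ctsh (4.72), Dmwd (4.67) and Ambp (4.50). For Slc4a7 the other probes gave -0.27 and -0.70, both called, so its direction depends on the probe. Among the lowest were the phosphodiesterase Enpp4 (-4.74 ± 0.06), the interferon-inducible Ifi202b (-4.70), Ms4a6c (-4.63), Cd36 (-4.53 ± 0.06), Clec4a2 (-4.44), Ifi203 (-4.29), Gbp3 (-4.11), the oxidase subunit Cybb (-4.10 ± 0.06) and Tgm2 (-4.08). Adjusted p-values of these genes from limma were 4.38e-06 or less. Groups that do not overlap were a condition for being named by rank in a comparison of 2 groups, and chance alone meets it for 10% of unchanged genes.

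Among called genes well above background on every array compared at single times, Rab15 (7.89 ± 0.24), Chst1 (6.63 ± 0.18) and Rhod (6.35 ± 0.21) were highest at 0 h, and Clec4a2 (-4.41 ± 0.13), Cybb (-4.28 ± 0.11) and Ppfia4 (-4.16 ± 0.15) lowest. At 1 h Epha2 (9.17 ± 0.31), Rab15 (7.65) and Chst1 (7.12) were highest and Clec7a (-7.14 ± 0.13), Il1b (-5.48 ± 0.26) and Cytip (-5.18 ± 0.19) lowest. Other Cytip probes gave -0.58, not called, and -1.26, called. Chst1 (8.61), Tnnt2 (6.59) and Galnt3 (6.16) were highest at 3 h, when Ifit1 (-8.04 ± 0.17), Il1a (-7.90 ± 0.25) and Rsad2 (-7.59 ± 0.20) were lowest. By 5 h Rab15 (6.85), Ranbp3l (6.68) and Phlda3 (6.62) were highest and Il1a (-9.15 ± 0.25), Clec7a (-8.38 ± 0.13) and Ifit3 (-8.22 ± 0.22) lowest.

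At 0 h, cholesterol synthesis had 18 of 23 members lower and 1 higher (median -1.23, camera adjusted p = 6.22e-10). Macrophage identity had 13 of 25 lower and 3 higher (median -0.96, camera adjusted p = 6.88e-06). Lipid handling and LXR targets had 11 of 20 lower and 3 higher (median -0.63, camera adjusted p = 0.00653). All these counts were the same adjusted over the list alone. Of the lipid genes, Scd1 was at -5.13 ± 0.47, Lpl at -3.12 ± 0.18 and Fabp4 at 3.17 ± 0.14, and Pltp was at least 6.90-fold lower. These 3 calls held with an estimated correlation (adjusted p = 0.0207, 0.0278 and 0.0278). With the slide run as a block the medians were -1.33 for cholesterol synthesis and -0.83 for macrophage identity. Within the run that holds both lines they were -1.39 and -0.94. The call of lipid handling ended with the filter on all arrays (adjusted p = 0.0661).

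The unfolded protein response had 23 of 28 members higher and 1 lower, the same adjusted over the list alone. Its median was 1.13 (camera adjusted p = 8.25e-07, and adjusted p = 0.109 with an estimated correlation). The median was 1.05 with the slide run as a block and 1.05 within the run that holds both lines. Of heat shock and p53 stress genes 11 of 18 were higher, the same adjusted over the list alone. Their median was 1.13 (camera adjusted p = 3.16e-06, and adjusted p = 0.108 with an estimated correlation), or 1.03 and 1.00 in the same run fits. Inflammatory mediators and enzymes had 13 of 23 higher and 4 lower, 15 and 4 adjusted over the list alone. Their median was 1.18, or 0.51 with dim genes at their bound (camera adjusted p = 0.00653, and adjusted p = 0.219 with an estimated correlation). Ptgs2 was at least 43.1-fold higher, Slpi higher by 4.67 ± 0.21 and Cfb at least 8.18-fold lower. The call of the mediators ended with the repaired normexp correction (median 0.10, adjusted p = 0.147).

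Interferon-stimulated genes had 21 of 42 members higher and 6 lower at 0 h, the same adjusted over the list alone. The median was 0.62 (camera adjusted p = 0.0305, and adjusted p = 0.366 with an estimated correlation), with Psmb9 at -2.39 ± 0.11 and Ifi47 at 2.29 ± 0.16. That call ended with the slide run as a block (adjusted p = 0.0836) and within the run that holds both lines (adjusted p = 0.0615). It also ended with quantile normalization (adjusted p = 0.0623), the deposited values (adjusted p = 0.0573), the repaired normexp correction (adjusted p = 0.149), no filter (adjusted p = 0.164) and the filter on all arrays (adjusted p = 0.0661). Without CAT 0 h replicate 2 the adjusted p was 0.0644.

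Oxidative phosphorylation genes were slightly lower at 0 h, 11 of 26 lower and 1 higher, as adjusted over the list alone. The median was -0.19 (camera adjusted p = 0.0483, and adjusted p = 0.606 with an estimated correlation), with Sdha at -0.98 ± 0.14 and Cox5b at -0.97 ± 0.17. The call ended with median scaling (median -0.73, adjusted p = 0.0779), the repaired normexp correction (-0.10, adjusted p = 0.131) and the filter on all arrays (adjusted p = 0.0661). It ended without Tbc1d23 0 h replicate 1 (median -0.09, adjusted p = 0.101), 0 h replicate 3 (0.074), 1 h replicate 2 (0.0536), 3 h replicate 2 (0.0503) or 5 h replicate 1 (0.0526). So it did without CAT 0 h replicate 1 (0.0511), replicate 2 (0.0625) or replicate 3 (0.0567), or CAT 3 h replicate 3 (0.0513).

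The lists that follow were not called as a group at 0 h (camera adjusted p in parentheses). Of 21 cytokines 9 were higher and 5 lower (0.636), with Tnfsf9 at 2.14 ± 0.15 and Tnf at 1.92 ± 0.13. Of 18 chemokines 8 were higher and 4 lower (0.115), with Ccl4 at 5.17 ± 0.13 and Ccl3 at 3.81 ± 0.25. Of 24 immediate early genes 9 were higher and 10 lower (0.644), with Ier3 at 4.28 ± 0.22 and Klf4 at -4.15 ± 0.18. Of 21 NF-kB targets 8 were higher and 6 lower, 8 and 7 adjusted over the list alone (0.805), with Traf1 at 2.80 ± 0.12 and Cd83 at -2.34 ± 0.11; their median of -0.08 and mean of 0.06 differ in sign. Of 16 negative regulators 8 were higher and 3 lower, 9 and 3 adjusted over the list alone (0.0956), with Dusp4 at 3.65 ± 0.14 and Irak3 at -1.93 ± 0.21. Of 19 NRF2 targets 9 were higher and 1 lower, 10 and 1 adjusted over the list alone (0.0697), with Hmox1 at 3.26 ± 0.27 and Osgin1 at 0.98 ± 0.19. Of 31 cell cycle genes 4 were higher and 12 lower, 4 and 13 adjusted over the list alone (0.0697), with Cdkn1a at 2.88 ± 0.17 and Ccnd1 at 1.74 ± 0.09. Of 28 lysosome and autophagy genes 7 were higher and 10 lower, 7 and 12 adjusted over the list alone (0.138), with Tfeb at -1.68 ± 0.36. Where a single pair of counts is given, adjusting over the list alone gave the same.

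Also not called at 0 h were TLR4 pathway components (0.493), pattern recognition receptors (0.132), antigen presentation (0.607), the Rab TBC family (0.834), trans-Golgi and endosome genes (0.834) and glycolysis and hypoxia (0.161).

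Markers of other cell types moved both ways at 0 h. The osteoclast markers Acp5 (-6.48 ± 0.43) and Atp6v0d2 (at least 5.06-fold) were lower, with 6 of 11 lower and 3 higher (0.138). The dendritic marker Itgax was lower (-2.53 ± 0.17), the single call among 7 (0.138). Higher were the T cell genes Cd5 (2.98 ± 0.20) and Lck (1.42 ± 0.15) of 5 tested (0.138). So were the B cell genes Vpreb1 (at least 19.9-fold) and Cd79b (at least 1.42-fold) of 3 tested. Of 9 granulocyte and erythroid genes S100a8 (at least 3.33-fold) and Epor (0.68 ± 0.27) were higher (0.379), and 1 call remained adjusted over the list alone. Of 4 fibroblast and epithelial markers Pdgfrb was lower (-2.44 ± 0.74) and Lum higher (1.53 ± 0.61). The other marker counts were the same adjusted over the list alone. At 0 h the CAT arrays measured 11 of 11 osteoclast, 7 of 7 dendritic, 4 of 5 T and NK, 1 of 3 B cell, 8 of 9 granulocyte and erythroid and 2 of 4 fibroblast markers above background. Of macrophage genes it was 25 of 25.

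At 5 h, 42 of 42 interferon-stimulated genes were lower in the Tbc1d23 line (median -4.60, camera adjusted p = 3.86e-05 with an estimated correlation), as were 19 of 21 cytokines (median -2.89), with 1 higher, and 17 of 18 chemokines (median -3.35). Macrophage identity genes stayed lower (15 of 25, 2 higher, median -0.91, adjusted p = 0.0164 with an estimated correlation). Adjusted over the list alone the counts were the same. The unfolded protein response was no longer called as a group (16 higher and 6 lower of 28, camera adjusted p = 0.0544, or 17 and 6 adjusted over the list alone).

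In the CAT line LPS raised inflammatory cytokines and immediate early genes within 1 h and interferon-stimulated genes by 3 h. The cytokine Il1b rose by a log2 of 10.58 ± 0.26 at 1 h (1530-fold), 13.12 ± 0.26 at 3 h and 13.39 ± 0.26 at 5 h, and the chemokine Cxcl10 by 8.05 ± 0.12, 9.27 ± 0.12 and 9.42 ± 0.12. The interferon-stimulated Ifit1 rose by 4.19 ± 0.17 at 1 h and 9.98 ± 0.17 at 3 h (1010-fold). Tnf, an early product of TLR4 signalling, rose by 7.07 ± 0.13 at 1 h and remained 6.48 above its start at 5 h.

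LPS changed 1138 genes in the CAT line at 1 h (552 higher, 586 lower), 5262 at 3 h (2437 and 2825) and 6287 at 5 h (2770 and 3517), of which 514, 2288 and 2916 at least 2-fold. With the replicate paired through its slide, 2645 were called at 1 h; with the slide run as a block 1738 were, and 1215, 5657 and 6805 at 1, 3 and 5 h within the run that holds both lines. Median scaling gave 317 higher and 102 lower at 1 h. Tnfaip3 (8.26 ± 0.13), Nfkbiz (7.54 ± 0.20) and Phlda1 (7.40 ± 0.15) were also among the highest at 1 h, and Txnip (-3.70 ± 0.11), Rgs2 (-2.65 ± 0.16) and Zkscan14 (-2.35 ± 0.16) the lowest. At 3 h Irg1 (current symbol Acod1; 8.31 ± 0.14), Cd40 (7.88 ± 0.22) and Penk (7.60 ± 0.63) followed the genes already given, and Sesn1 (-4.38 ± 0.21), Kbtbd11 (-4.32 ± 0.17) and Klhl6 (-4.10 ± 0.16) fell most. At 5 h Ifit1 (10.66 ± 0.17), Cd40 (8.85 ± 0.22), Zbp1 (8.69 ± 0.16) and Isg20 (8.57 ± 0.12) stood beside Il1b and Cxcl10, and Ranbp3l (-5.04 ± 0.18), Amz1 (-4.48 ± 0.19) and Bmf (-4.42 ± 0.20) fell most; the other Bmf probe gave 0.65, not called. Adjusted p-values of these genes from limma were 1.19e-08 or less.

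At 1 h in the CAT line 21 of 24 immediate early genes rose (median 3.81, adjusted p = 8.82e-07), led by Nr4a1 (6.98 ± 0.22) and Maff (6.55 ± 0.24). Of NF-kB targets 18 of 21 rose, 20 adjusted over the list alone (median 2.49, adjusted p = 8.82e-07). Of cytokines 12 of 21 rose (median 1.97, adjusted p = 9.25e-07), and of chemokines 10 of 18 (median 1.12, adjusted p = 1.33e-05). Of inflammatory mediators 13 of 23 rose, 14 adjusted over the list alone (median 0.80, adjusted p = 1.57e-05). These camera values used an estimated correlation, and the other counts were the same adjusted over the list alone. Interferon-stimulated genes had 7 of 42 higher and 1 lower, 8 and 2 adjusted over the list alone. Their median was -0.02 and their mean 0.42, while camera called them up (adjusted p = 0.000155, and adjusted p = 0.0895 with an estimated correlation); the median was 0.01 with the deposited values and 0.11 with median scaling. Without single arrays it ranged from -0.14 (CAT 1 h replicate 1) to 0.08 (CAT 1 h replicate 2), and it was 0.02 and -0.08 without CAT 0 h replicates 1 and 2, -0.01 without CAT 0 h replicate 3 and 0.03 without CAT 1 h replicate 3.

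At 5 h in the CAT line 42 of 42 interferon-stimulated genes were higher (median 4.81, adjusted p = 1.69e-05), led by Rsad2 (11.39 ± 0.20) and Ifit3 (11.10 ± 0.22). They were so at 3 h too (42 of 42, median 3.86). Of cytokines 19 of 21 were higher (median 4.10, or 3.34 with dim genes at their bound, adjusted p = 2.79e-05), with Il1a at least 1920-fold and Il6 at least 960-fold. Of chemokines 18 of 18 were higher (median 5.59, adjusted p = 0.00011), with Cxcl2 at least 792-fold and Cxcl11 at least 781-fold. Of NF-kB targets 20 of 21 were higher (median 2.94, adjusted p = 0.00017), with Traf1 at 6.01 ± 0.12 and Tnfaip3 at 5.92 ± 0.13. Inflammatory mediators had 20 higher and 3 lower of 23 (median 4.84, adjusted p = 0.000192), with Hdc at 10.12 ± 0.20 and Ptgs2 at least 318-fold. Immediate early genes had 20 higher and 2 lower of 24 (median 1.99, adjusted p = 0.0115), with Myc at 6.25 ± 0.23 and Dusp2 at 4.64 ± 0.11. Negative regulators had 10 higher and 4 lower of 16 (median 1.45, adjusted p = 0.0338), with Cish at least 410-fold and Socs3 at 5.07 ± 0.16. Pattern recognition receptors had 17 of 21 higher (median 1.87, adjusted p = 6.01e-05), with Fpr1 at 4.70 ± 0.92 and Clec4e at 4.53 ± 0.19. Antigen presentation genes had 13 of 18 higher (median 1.01, adjusted p = 0.00011), with Cd40 at 8.85 ± 0.22 and Cd80 at 5.07 ± 0.15. Of T and NK markers 3 of 5 were higher (adjusted p = 0.0338), with Cd247 at least 31.4-fold and Lck at 2.59 ± 0.15. These camera values used an estimated correlation, and every count was the same adjusted over the list alone.

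Cell cycle genes had 25 of 31 lower and 1 higher at 5 h in the CAT line, 28 and 1 adjusted over the list alone. The median was -0.99 (camera adjusted p = 7.24e-10, and adjusted p = 0.0513 with an estimated correlation), with Cdc6 at -2.74 ± 0.15, Ccne2 at -2.62 ± 0.16 and the inhibitor Cdkn1a at 2.42 ± 0.17. Cholesterol synthesis had 13 of 23 lower and 1 higher, 15 and 1 adjusted over the list alone. Its median was -0.44 (camera adjusted p = 0.00124, and adjusted p = 0.104 with an estimated correlation), with Dhcr7 at -2.83 ± 0.17. The Rab TBC family had 17 of 31 lower and 2 higher, the same adjusted over the list alone. Its median was -0.45 (camera adjusted p = 0.00356, and adjusted p = 0.107 with an estimated correlation), with Tbc1d2 at -3.99 ± 0.28 and Grtp1 at -3.31 ± 0.15. The unfolded protein response had 11 of 28 higher and 1 lower, 11 and 2 adjusted over the list alone. Its median was 0.25 (camera adjusted p = 0.00133, and adjusted p = 0.203 with an estimated correlation), with Chac1 at 4.11 ± 0.29 and Trib3 at 3.73 ± 0.21. TLR4 pathway components had 13 of 27 higher and 4 lower, 14 and 5 adjusted over the list alone. Their median was 0.39 (camera adjusted p = 0.00713, and adjusted p = 0.203 with an estimated correlation), with Ikbke at 4.85 ± 0.30 and Irak2 at 2.59 ± 0.11.

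Not called as a group at 5 h in the CAT line (camera adjusted p in parentheses) were lipid handling (0.433), glycolysis and hypoxia (0.0595), lysosome and autophagy (0.437), NRF2 targets (0.265), heat shock and p53 stress (0.395), trans-Golgi and endosome genes (0.239) and oxidative phosphorylation (0.61).

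Among markers at 5 h in the CAT line, macrophage identity had 9 of 25 higher and 8 lower (0.618), with Cebpa at -2.24 ± 0.12 and Fcgr1 at 2.00 ± 0.18. Osteoclast markers had 5 of 11 higher and 2 lower (0.067), with Jdp2 at 4.27 ± 0.20 and Ocstamp at 4.14 ± 0.24. Dendritic markers had 2 of 7 higher (0.395), Itgax at 2.33 ± 0.17 and Fscn1 at 1.46 ± 0.41. The B cell marker Cd79b was at least 2.18-fold higher, and the fibroblast markers Lum and Dcn at least 4.31-fold and 2.70-fold. The other counts were the same adjusted over the list alone.

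In the Tbc1d23 line LPS raised many of the same genes by less. Tnf rose by 5.26 at 1 h and 2.10 at 5 h. From a higher start it reached 6.54 to 6.86 at 1 h (CAT 6.55 to 6.59). Ifit1 rose by 0.24 (not called) at 1 h and 2.14-fold at 5 h. Il1b rose at least 40.2-fold at 1 h and 121-fold at 5 h. In all, 250 genes changed at 1 h (126 higher, 124 lower), 1024 at 3 h (526 and 498) and 959 at 5 h (456 and 503), with 180, 419 and 316 at least 2-fold. These counts share a spread with the less variable CAT arrays and fell with only the groups compared fitted. Pairing replicates through the slide gave 702, 2526 and 2351, and the slide run as a block 385, 1621 and 1556. Median scaling split them into 122 higher and 25 lower, 450 and 31, and 204 and 18, quantile normalization the 1 h genes into 177 and 71, the deposited values into 177 and 64, and the repaired normexp correction into 121 and 48. Under median scaling the median of all genes in these responses was 0.47, 0.51 and 0.23, against -0.09, -0.04 and -0.03.

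Of the 456 genes higher at 5 h in the Tbc1d23 line, 408 were also higher in the CAT line, where independent calls would share 83.7. Of the 503 lower 411 were shared, against 117. At 1 h 120 higher and 53 lower genes were shared, against 4.61 and 4.81, and at 3 h 474 and 350, against 84.9 and 93.2. At 5 h 18 of 21 NF-kB targets rose, 19 adjusted over the list alone (median 1.69, adjusted p = 5.64e-06). Of 21 cytokines 11 rose, the same adjusted over the list alone (median 0.66, adjusted p = 6.76e-05). Of 18 chemokines 9 rose, 10 adjusted over the list alone (median 0.69, adjusted p = 0.000392). Inflammatory mediators had 14 of 23 higher and 1 lower, the same adjusted over the list alone (median 1.49, adjusted p = 0.000128). Immediate early genes had 13 of 24 higher and 3 lower, 15 and 3 adjusted over the list alone (median 0.67, adjusted p = 0.0201). These camera values used an estimated correlation. Interferon-stimulated genes had 7 of 42 higher and 4 lower, 8 and 8 adjusted over the list alone (median -0.17, camera adjusted p = 0.823).

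**Figure D2:**
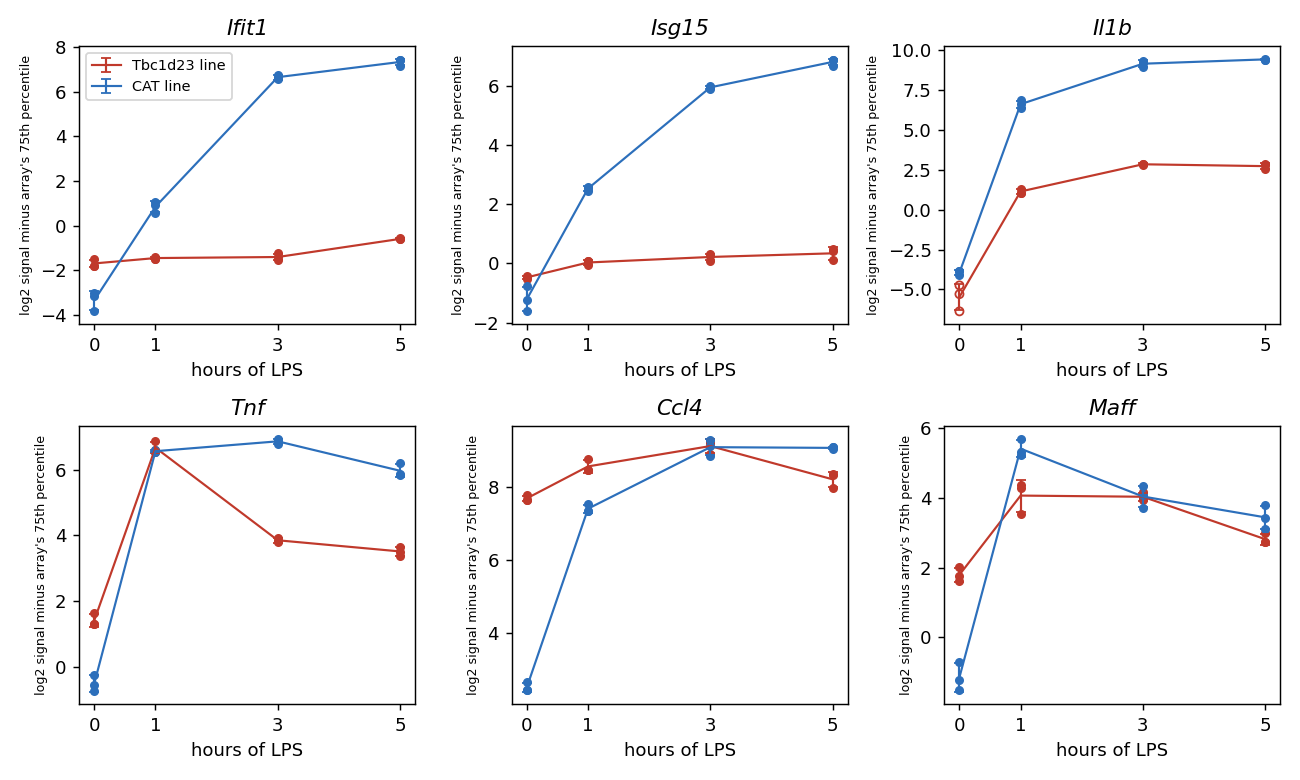
Log2 signal relative to each array's 75th percentile against hours of LPS for 6 genes, each point an array (open where not well above background), with group means joined and bars of 1 SD (n = 3), by line of cells. Ifit1 and Isg15 rise steeply only in the CAT arrays, while Ccl4 and Maff start higher in the Tbc1d23 arrays, by 5.17 and 2.93.

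The LPS response itself was tested for a difference between the lines. The antiviral genes Ifit1, Isg15 and Isg20 rose by 10.66, 8.02 and 8.57 at 5 h in the CAT line. In the Tbc1d23 line Ifit1 rose 2.14-fold and Isg15 by 0.81, and Isg20 (0.37) was not called. The interaction values were -9.57 ± 0.24, -7.21 ± 0.21 and -8.21 ± 0.16. The response of Tnf was smaller by -4.38 at 5 h. For Ccl4 the response was smaller by -6.02 ± 0.19, from a start higher by 5.17 ± 0.13 to a level lower by -0.86, and Maff started higher by 2.93 and ended lower by -0.63, so smaller responses do not always mean much lower levels.

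The interaction was called for 364 genes at 1 h (96 higher, 268 lower in the Tbc1d23 line), 2520 at 3 h (1255 and 1265) and 3507 at 5 h (1903 and 1604), with 272, 1437 and 2005 at least 2-fold. At least 16-fold were 14 at 1 h, 124 at 3 h and 181 at 5 h with a lower value, and 11 at 5 h with a higher one. With the replicate paired through its slide 880, 4581 and 6002 were called, with the slide run as a block 553 at 1 h, and within the run that holds both lines 238, 1646 and 2565. Quantile normalization split the 3 h genes into 1809 higher and 1121 lower and the 5 h genes into 2703 and 1390; median scaling gave 9 and 61 at 1 h and 729 and 379 at 3 h. The median of all genes moved from 0, -0.02 and -0.01 at 1, 3 and 5 h to 0.07, 0.14 and 0.15 with quantile normalization, and to 0.42, 0.55 and 0.29 with median scaling.

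The genes in this paragraph rank highest and lowest among called genes well above background on every array compared. At 1 h the lowest interaction values among these were those of Maff (-4.28 ± 0.34), Ccl4 (-4.01 ± 0.19), Ifit1 (-3.95 ± 0.24), Traf1 (-3.79 ± 0.17) and Ppp1r15a (-3.76 ± 0.36), and the highest, for genes that fell less, those of Txnip (3.04 ± 0.16), Rgs2 (2.67 ± 0.23), Zkscan14 (1.87 ± 0.23), Zfp30 (1.82 ± 0.41) and Alkbh4 (1.79 ± 0.20). The call of Zfp30 ended within the run that holds both lines (1.69, adjusted p = 0.507), with median scaling (2.25, adjusted p = 0.0541), with the repaired normexp correction (0.60, adjusted p = 0.483), and without CAT 1 h replicate 1 (1.66, adjusted p = 0.0567) or CAT 0 h replicate 2 (1.63, adjusted p = 0.0577). At 3 h Ifit1 (-9.69 ± 0.24), Cmpk2 (-6.59 ± 0.20), Mx2 (-6.48 ± 0.25), Isg15 (-6.47 ± 0.21) and Isg20 (-6.30 ± 0.16) were lowest and Bmf (3.45 ± 0.29), Klhl6 (3.32 ± 0.22), Klhl24 (3.22 ± 0.24), Slc26a11 (3.20 ± 0.37) and Sesn1 (3.08 ± 0.30) highest. At 5 h Zbp1 (-8.12 ± 0.23) and Cmpk2 (-7.80 ± 0.20) joined Ifit1, Isg20 and Isg15, and Bmf (5.52 ± 0.29), Ranbp3l (4.31 ± 0.25), Sesn1 (3.85 ± 0.30), Fam131a (3.64 ± 0.24) and Neurl3 (3.38 ± 0.52) were highest. The other Bmf probe gave -0.46 at 3 h and -0.44 at 5 h, neither called. Adjusted p-values from limma were 6.07e-05 or less at 3 and 5 h and 0.0167 or less at 1 h.

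**Figure D3:**
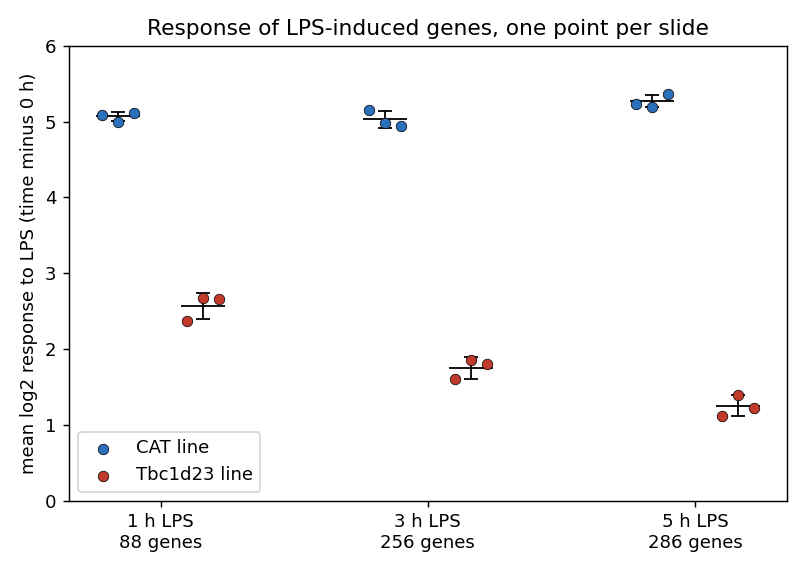
Mean log2 LPS response of the LPS-induced gene sets against hours of LPS, each point a slide, that is, a replicate, with horizontal lines at the means and bars of 1 SD (n = 3). The CAT slides stay between 4.95 and 5.36 while the Tbc1d23 slides lie between 2.37 and 2.67 at 1 h and between 1.12 and 1.40 at 5 h.

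LPS-induced genes as a set responded less in the Tbc1d23 line at each time. Over 88 genes at 1 h, 256 at 3 h and 286 at 5 h, the median interaction was -2.38, -2.98 and -3.64, or -2.07, -2.76 and -3.52 with dim genes at their bound (camera adjusted for an estimated correlation, p = 6.42e-12, 4.22e-09 and 3.31e-09). The response was smaller for 84, 247 and 278 of these genes and larger for 4, 9 and 8; 66, 222 and 256 smaller responses were called. Averaged over the set, each slide's response was 5.07 ± 0.06, 5.03 ± 0.11 and 5.27 ± 0.08 in the CAT line and 2.57 ± 0.17, 1.75 ± 0.14 and 1.25 ± 0.14 in the Tbc1d23 line (SD, n = 3). The sets started higher in the Tbc1d23 line by medians of 0.77, 0.68 and 0.74 and ended lower by -1.33, -2.24 and -3.11. The slide run as a block cannot move these medians, since each slide holds all 4 times. Within the run that holds both lines they were -2.16, -2.94 and -3.80.

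**Figure D4:**
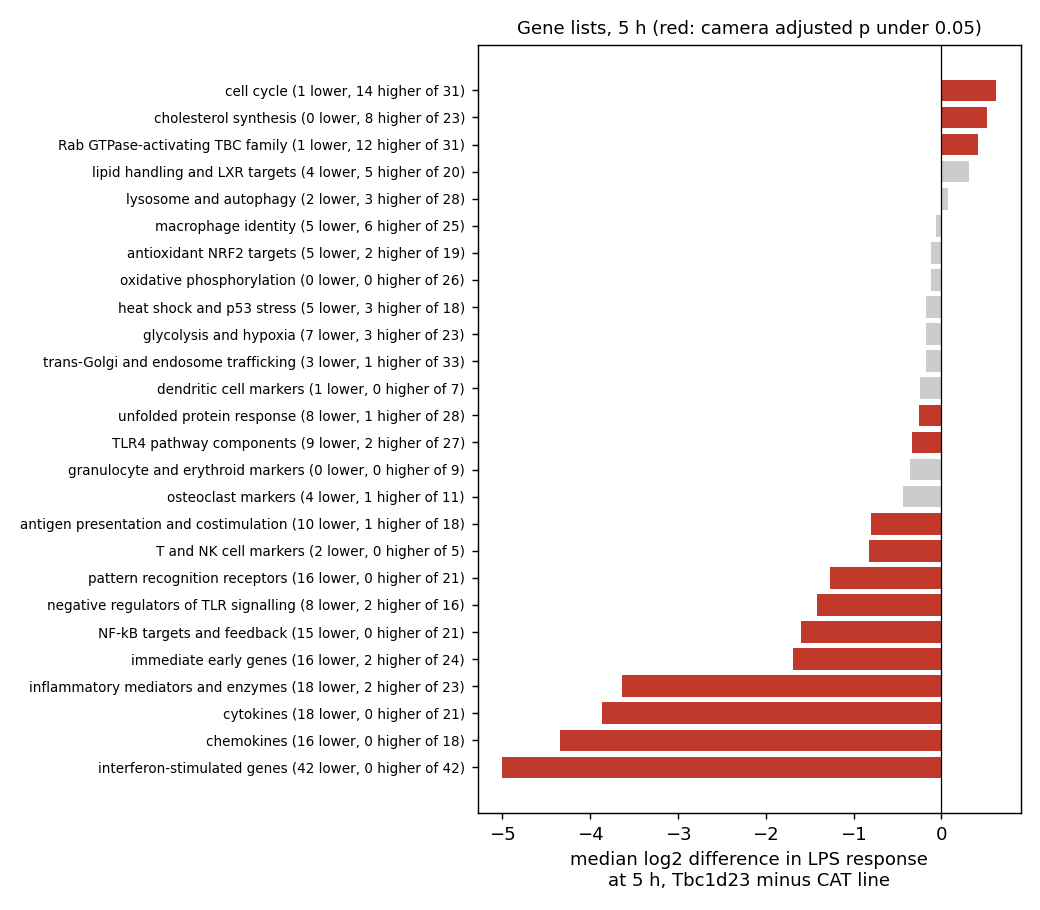
Median log2 interaction at 5 h (Tbc1d23 response minus CAT response) of 26 gene lists, 1 bar each, with the numbers of members called lower and higher; red bars have a camera adjusted p under 0.05 with the preset correlation. Interferon-stimulated genes have the lowest median (-5.00) and cell cycle genes the highest (0.62); the unfolded protein response, at -0.26, turns to 0.03 with median scaling.

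At 5 h the response was smaller for 42 of 42 interferon-stimulated genes, the same adjusted over the list alone. The median was -5.00, or -4.94 with dim genes at their bound (camera adjusted p = 1.11e-06 with an estimated correlation), led by Ifit3 (-9.82 ± 0.32). Mx1, at least 37.2-fold higher after LPS in the CAT line, was then at least 36.6-fold lower in the Tbc1d23 line than in the CAT line. At 3 h 39 of 42 responses were smaller, 41 adjusted over the list alone (median -4.15, adjusted p = 1.22e-06). Within the run that holds both lines the medians were -5.07 at 5 h and -4.11 at 3 h. At 1 h Isg15 (-3.24 ± 0.21) was among 8 smaller responses, with 1 larger, or 8 and 2 adjusted over the list alone. Median (0.10), mean (-0.40) and camera (down, adjusted p = 0.0277, and adjusted p = 0.282 with an estimated correlation) differ in sign there. That call ended with the replicate paired through its slide (adjusted p = 0.195), with the slide run as a block (adjusted p = 0.108) and with no filter (adjusted p = 0.322). It ended without Tbc1d23 0 h replicate 2 (median 0.17, adjusted p = 0.0762), Tbc1d23 1 h replicate 3 (0.05, adjusted p = 0.156), CAT 1 h replicate 1 (0.20, adjusted p = 0.147) or CAT 0 h replicate 2 (adjusted p = 0.129). Without Tbc1d23 0 h replicate 1, CAT 1 h replicate 2 or CAT 0 h replicate 3 the median was 0.04, 0.03 and 0.06.

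Of 21 cytokines the response was smaller for 8 at 1 h, 18 at 3 h and 18 at 5 h. With p adjusted over the list alone it was 9 with 1 larger, 19 and 18. The medians were -0.84, -3.04 and -3.86, or -0.58, -2.59 and -2.97 with dim genes at their bound (camera adjusted p = 0.000111, 6.94e-06 and 1.27e-05 with an estimated correlation). Without Tbc1d23 0 h replicate 1 the 1 h median of cytokines was -0.53. At 5 h Il1a was at least 1920-fold above its start in the CAT line and at least 2.37-fold in the Tbc1d23 line, and Il6 at least 960-fold and 1.27-fold. Ifnb1 was at least 98.8-fold above its start at 1 h in the CAT line and at least 4.22-fold in the Tbc1d23 line. Of 18 chemokines the response was smaller for 9, 14 and 16, or 9, 15 and 16 with 1 larger adjusted over the list alone. Their medians were -1.08, -3.63 and -4.34 (adjusted p = 5.55e-05, 6.15e-05 and 6.5e-05 with an estimated correlation). Cxcl11 was at least 781-fold above its start at 5 h in the CAT line and 2.53 on the log2 scale in the Tbc1d23 line. Within the run that holds both lines the medians were -0.66, -2.90 and -3.83 for cytokines and -0.90, -3.33 and -4.43 for chemokines.

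Immediate early genes had 13 of 24 responses smaller at 1 h, 12 with 5 larger at 3 h and 16 with 2 larger at 5 h. Adjusted over the list alone these were 16 with 1, 14 with 5 and 16 with 2. The medians were -1.26, -0.52 (0.05 under median scaling) and -1.69. With an estimated correlation the camera adjusted p was 0.00035, 0.218 and 0.0148, and at 3 h it was 0.00159 with the preset value. Dusp1 was at -3.23 ± 0.28, -3.99 ± 0.28 and -3.60 ± 0.28, and Fosl1 at -3.72 ± 0.19 at 5 h. NF-kB targets had 13 of 21 smaller at 1 h, 17 with 1 larger at 3 h and 15 at 5 h. Adjusted over the list alone these were 15, 18 with 1, and 17. The medians were -1.27, -1.47 and -1.60 (adjusted p = 2.74e-05, 0.000666 and 0.00122 with an estimated correlation). Tnfaip3 was at -4.47 ± 0.19 and Nfkbiz at -3.27 ± 0.28 at 5 h, and Cd83, at 0.89, had the larger response at 3 h. Inflammatory mediators had 7 of 23 smaller at 1 h, 17 with 3 larger at 3 h and 18 with 2 larger at 5 h. Adjusted over the list alone the 1 h count was 11 and the others the same. The medians were -0.76, -3.05 and -3.64 (adjusted p = 0.000111, 0.000404 and 0.000213 with an estimated correlation). Hdc was at -7.11 ± 0.29 and Saa3 at -6.88 ± 0.54 at 5 h, when Edn1 was at least 48.0-fold lower in the Tbc1d23 line than in the CAT line.

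Negative regulators of TLR signalling had 5 of 16 responses smaller at 1 h, 7 with 3 larger at 3 h and 8 with 2 larger at 5 h. Adjusted over the list alone these were 6, 7 with 3, and 9 with 2. The medians were -0.36 (0.07 under median scaling), -0.46 (0.12 under median scaling) and -1.42. The camera adjusted p was 0.00157, 0.0432 and 0.0155 with an estimated correlation. At 5 h Trim30a was at -4.96 ± 0.27 and Socs1 at -4.40 ± 0.29. Pattern recognition receptors had 4, 10 and 16 of 21 smaller, or 5, 11 and 17 adjusted over the list alone. The medians were -0.39 (0.04 under median scaling), -0.76 and -1.27 (adjusted p = 0.00512, 0.000648 and 4.2e-05 with an estimated correlation). The 1 h median of these receptors was -0.20 and -0.09 without Tbc1d23 1 h replicates 1 and 3, -0.18 without CAT 0 h replicate 1 and -0.02 without CAT 1 h replicate 3. At 5 h Fpr1 was at -4.92 ± 1.30 and Nod1 at -3.66 ± 0.38. Antigen presentation genes had 5, 6 and 10 of 18 smaller, with 1 larger at 5 h, the same adjusted over the list alone. The 1 h median was -0.11, but 0.08 under quantile normalization, 0.06 with the deposited values and 0.32 under median scaling. Without Tbc1d23 0 h replicate 1 or 2 it was -0.05 and -0.20, without Tbc1d23 1 h replicate 2 or 3 -0.07 and -0.07, without CAT 0 h replicate 1 or 3 -0.06 and -0.22, and without CAT 1 h replicate 1 or 3 -0.21 and -0.07. The 3 h median was -0.56, but 0.02 under median scaling, and the 5 h median -0.80. The adjusted p was 0.00673, 0.000666 and 0.000263 with an estimated correlation, and the 1 h call ended with the filter on all arrays (adjusted p = 0.172). At 5 h Cd40 was at -5.11 ± 0.31 and Cd80 at -4.38 ± 0.21.

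T and NK markers had 2 of 5 responses smaller at 3 h and 2 at 5 h, the same adjusted over the list alone, with Lck at -1.99 ± 0.21 at 5 h. The medians were -0.47 (0.11 under median scaling) and -0.82, and -0.87 and -0.45 within the run that holds both lines. At 3 h the median was -0.31 without Tbc1d23 3 h replicate 2 or 0 h replicate 3, and -0.20, -0.76 and -0.30 without CAT 0 h replicate 1, 0 h replicate 3 or 3 h replicate 2. At 5 h it was -0.44, -1.52 and -0.48 without Tbc1d23 5 h replicate 1, 5 h replicate 3 or 0 h replicate 3. The camera adjusted p was 0.0252 and 0.0101, and adjusted p = 0.0541 and 0.031 with an estimated correlation. The 3 h call ended with the replicate paired through its slide (adjusted p = 0.0696). Both calls ended with the repaired normexp correction (adjusted p = 0.135 and 0.0519) and with no filter (adjusted p = 0.113 and 0.127). Osteoclast markers had 4 of 11 smaller at 3 h, the same adjusted over the list alone (median -0.88, or -0.55 without Tbc1d23 0 h replicate 1, adjusted p = 0.0432 with an estimated correlation), with Ocstamp at -2.94 ± 0.33 and Jdp2 at -2.63 ± 0.29.

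Interaction medians of cell cycle, cholesterol synthesis and Rab TBC genes lay above 0 at 3 and 5 h, but of these 6 calls 5 were lost with an estimated correlation and that of cholesterol synthesis at 3 h was kept (adjusted p = 0.0432). Cell cycle genes had 7 of 31 values larger and 1 smaller at 3 h and 14 and 1 at 5 h. Adjusted over the list alone these were 10 and 1, and 17 and 1. The medians were 0.52 and 0.62 (camera adjusted p = 7.49e-06 and 1.54e-07, and adjusted p = 0.152 and 0.0948 with an estimated correlation). At 5 h Cdc6 was at 2.04 ± 0.21 and Mcm2 at 1.83 ± 0.18. Cholesterol synthesis had 10 of 23 larger at 3 h and 8 at 5 h, or 12, and 10 with 1 smaller, adjusted over the list alone. The medians were 0.51 and 0.52 (camera adjusted p = 2.18e-05 and 0.000162, and adjusted p = 0.0611 at 5 h with an estimated correlation). At 5 h Dhcr7 was at 2.64 ± 0.24 and Mvd at 1.72 ± 0.22. The Rab TBC family had 9 of 31 larger and 2 smaller at 3 h and 12 and 1 at 5 h, the same adjusted over the list alone. The medians were 0.39 and 0.42 (camera adjusted p = 0.00508 and 0.00256, and adjusted p = 0.133 and 0.0948 with an estimated correlation), and that at 5 h was 0.27 without Tbc1d23 5 h replicate 3. At 5 h Tbc1d2 was at 2.77 ± 0.40 and Grtp1 at 2.54 ± 0.22.

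Further list calls were weaker. The unfolded protein response at 5 h had 8 of 28 smaller and 1 larger, 9 and 1 adjusted over the list alone, with Chac1 at -4.01 ± 0.41 and Trib3 at -3.83 ± 0.29. Its median was -0.26, but 0.03 under median scaling (camera adjusted p = 0.00256, and adjusted p = 0.251 with an estimated correlation). TLR4 pathway components had 8 of 27 smaller and 2 larger at 3 h and 9 and 2 at 5 h. With p adjusted over the list alone these were 10 and 3, and 10 and 2. The medians were -0.18 (0.40 under median scaling, -0.31 without Tbc1d23 3 h replicate 3) and -0.33, with Ikbke at -2.16 ± 0.43 and Irak2 at -1.42 ± 0.16 at 5 h. The camera adjusted p was 0.0277 and 0.0175, and adjusted p = 0.311 and 0.269 with an estimated correlation. Both calls ended with median scaling (adjusted p = 0.214 and 0.0779) and with no filter (adjusted p = 0.179 and 0.165). That at 3 h ended with the filter on all arrays (0.0651), and without Tbc1d23 3 h replicate 1 (0.0511), Tbc1d23 0 h replicate 3 (0.0576), CAT 0 h replicate 2 (0.0528) or CAT 3 h replicate 3 (0.0745).

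At 1 h cholesterol synthesis had 3 of 23 responses smaller, with Insig1 at -1.22 ± 0.24. The median was -0.15, but 0.28 under median scaling (camera adjusted p = 0.0417, and adjusted p = 0.282 with an estimated correlation). Glycolysis and hypoxia had 2 of 23 smaller, Ankrd37 at -1.55 ± 0.21 and Vegfa at -1.38 ± 0.31. Their median was -0.07, but 0.36 under median scaling (camera adjusted p = 0.0492, and adjusted p = 0.253 with an estimated correlation). These counts were the same adjusted over the list alone. Heat shock and p53 stress had 3 of 18 smaller, 5 adjusted over the list alone, with Mdm2 at -1.59 ± 0.13 and Pmaip1 at -1.11 ± 0.22. Their median was -0.21, but 0.22 under median scaling and -0.06 without CAT 0 h replicate 1 (camera adjusted p = 0.000212, and adjusted p = 0.145 with an estimated correlation).

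The 1 h calls of cholesterol synthesis and glycolysis ended with the replicate paired through its slide (adjusted p = 0.0816 and 0.0865), the slide run as a block (0.0746 and 0.0611), median scaling (0.304 and 0.204) and no filter (0.322 and 0.322). That of cholesterol synthesis ended with fry (0.0582) and within the run that holds both lines (median -0.09, adjusted p = 0.177); without Tbc1d23 0 h replicate 1 the median was -0.06. It ended without Tbc1d23 0 h replicate 2 (median -0.04, adjusted p = 0.146), 1 h replicate 3 (0.156) or 3 h replicate 2 (0.0511), or without CAT 0 h replicate 2 (0.0695), 0 h replicate 3 (0.123) or 1 h replicate 1 (0.0833). That of glycolysis ended with the filter on all arrays (0.057) and the mean of probes (0.139). Its median was -0.12 within the run that holds both lines, -0.14 and -0.17 without Tbc1d23 1 h replicate 2 or 0 h replicate 3, and -0.12 without CAT 1 h replicate 1. It ended without Tbc1d23 0 h replicate 2 (median -0.04, adjusted p = 0.146), 1 h replicate 3 (0.173), 3 h replicate 1 (0.053), 3 h replicate 2 (0.0535), 3 h replicate 3 (0.0523) or 5 h replicate 2 (0.0542). So it did without CAT 0 h replicate 1 (median 0, adjusted p = 0.071), 0 h replicate 2 (0.0897), 1 h replicate 2 (median -0.02, adjusted p = 0.0717), 1 h replicate 3 (median -0.04, adjusted p = 0.201), 3 h replicate 2 (0.0522), 5 h replicate 1 (0.0543), 5 h replicate 2 (0.0517) or 5 h replicate 3 (0.0521).

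Some lists were not called for the interaction at 5 h (camera adjusted p in parentheses). Trans-Golgi and endosome genes had 1 of 33 larger and 3 smaller, 1 and 1 adjusted over the list alone (0.181). Lipid handling had 5 of 20 larger and 4 smaller, 6 and 4 adjusted over the list alone (0.437). Glycolysis and hypoxia had 3 of 23 larger and 7 smaller, 4 and 8 adjusted over the list alone (0.12). Lysosome and autophagy had 3 of 28 larger and 2 smaller (0.727). NRF2 targets had 2 of 19 larger and 5 smaller (0.109), with Slc7a11 at -3.95 ± 0.22 and Mt2 at -2.45 ± 0.29. Heat shock and p53 stress had 3 of 18 larger and 5 smaller (0.534). Macrophage identity had 6 of 25 larger and 5 smaller, 7 and 6 adjusted over the list alone (0.936), with Cebpa at 2.81 ± 0.16 and Fcgr1 at -2.37 ± 0.25; its median was -0.06 while camera leaned up. Osteoclast markers had 1 of 11 larger and 4 smaller (0.085), and of 7 dendritic markers Itgax was smaller (0.489). At 5 h the B cell marker Cd79b was at least 2.14-fold lower in the Tbc1d23 line than in the CAT line, and the fibroblast markers Lum and Dcn at least 4.23-fold and 2.66-fold. Where no second pair of counts is given, adjusting over the list alone left the counts the same.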

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

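The genes, lists and sets below were flagged because the LPS response differed between the Tbc1d23 and CAT lines in a test of that difference (the interaction); the place of Tbc1d23 replicate 3 and the line differences at 0 h were not flagged but are weighed too. Chosen only after the result was seen were the tests of the starting level, of probes near background, of line differences other than the construct, of the slide run and of other cell types. The splits of the samples and the tests of probe pairs and of the noise of dim probes were written down before their results were seen.

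The response differed for 364 genes at 1 h, 2520 at 3 h and 3507 at 5 h. Over the LPS-induced genes the median log2 difference was -2.38, -2.98 and -3.64. At 1 h the genes named by rank were Txnip (3.04), Rgs2 (2.67), Zkscan14 (1.87), Zfp30 (1.82), Alkbh4 (1.79), Maff (-4.28), Ccl4 (-4.01), Ifit1 (-3.95), Traf1 (-3.79) and Ppp1r15a (-3.76). At 3 h they were Bmf (3.45), Klhl6 (3.32), Klhl24 (3.22), Slc26a11 (3.20), Sesn1 (3.08), Ifit1 (-9.69), Cmpk2 (-6.59), Mx2 (-6.48), Isg15 (-6.47) and Isg20 (-6.30). At 5 h they were Bmf (5.52), Ranbp3l (4.31), Sesn1 (3.85), Fam131a (3.64), Neurl3 (3.38), Ifit1 (-9.57), Isg20 (-8.21), Zbp1 (-8.12), Cmpk2 (-7.80) and Isg15 (-7.21).

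List medians at 1, 3 and 5 h were -0.84, -3.04 and -3.86 for cytokines, -1.08, -3.63 and -4.34 for chemokines and 0.10, -4.15 and -5.00 for interferon-stimulated genes. They were -1.26, -0.52 and -1.69 for immediate early genes, -1.27, -1.47 and -1.60 for NF-kB targets and -0.36, -0.46 and -1.42 for negative regulators. Inflammatory mediators had -0.76, -3.05 and -3.64, pattern recognition receptors -0.39, -0.76 and -1.27, antigen presentation -0.11, -0.56 and -0.80 and cholesterol synthesis -0.15, 0.51 and 0.52. Lists flagged at 3 and 5 h were TLR4 pathway components (-0.18 and -0.33), the Rab TBC family (0.39 and 0.42), cell cycle (0.52 and 0.62) and T and NK markers (-0.47 and -0.82). Flagged at 1 time were glycolysis (-0.07) and heat shock and p53 stress (-0.21) at 1 h, osteoclast markers (-0.88) at 3 h and the unfolded protein response (-0.26) at 5 h. With an estimated correlation the calls were lost of TLR4 components (adjusted p = 0.311 and 0.269), the Rab TBC family (0.133 and 0.0948) and cell cycle (0.152 and 0.0948) at 3 and 5 h, glycolysis (0.253), heat shock and p53 stress (0.145) and interferon-stimulated genes (0.282) at 1 h and the unfolded protein response (0.251) at 5 h. So were those of cholesterol synthesis at 1 and 5 h (0.282 and 0.0611), immediate early genes (0.218) and T and NK markers (0.0541) at 3 h. Under median scaling the medians of glycolysis, heat shock and p53 stress and the unfolded protein response were 0.36, 0.22 and 0.03 there.

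The LPS-induced genes responded less in the Tbc1d23 line at 5 h. A higher start of these genes is not the whole cause, since their level at 5 h was lower too, by a median of -3.11. Probes near background are not the whole cause either: over the 143 of 286 genes well above background on all arrays the median was -3.06. A difference between the lines other than the construct stays open, because there was 1 line per construct, so line and construct cannot be told apart. The Tbc1d23 probes do not settle it: the brightest differed by 0.04 on average (0.40 with the slide run as a block), another by 0.50, and the part of the transcript the construct carries is not given in the sources used here.

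Tbc1d23 replicate 3 lay apart from replicates 1 and 2 on the principal component that held 8.4% of the variance. Its deviation correlated at 0.08 (0.03 to 0.13, 95% interval, 3605 genes) between probes of the same gene, as the planned test said probe-specific hybridization or printing differences would give, against 0.16 to 0.30 for CAT replicates. Replicate 1 minus replicate 2 of the Tbc1d23 line gave 0.05 (0.00 to 0.10), so the low value does not set replicate 3 apart. Noise of dim probes stays open: over the 5008 genes with the highest signal its median absolute deviation was 0.24, between the limits set, against 0.10 to 0.19 for the other replicates. The slide run cannot be told apart from it, since both other Tbc1d23 slides (2) are in another run, and no biological explanation was tested.

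Many genes differed between the lines at 0 h. Dilution by cells of another type stays open, since such cells could express the 3 macrophage genes called higher. Probe-specific hybridization or printing differences stay open for part of it: line differences correlated at 0.53 (0.49 to 0.56, 3603 genes) between probes of the same gene, less than the 0.85 of the CAT response. The slide run stays open: 5223 genes were called within the run that holds both lines, but with 1 Tbc1d23 array against 3 CAT arrays, so a deviation of that slide counts as a line difference. The construct and other differences between the lines stay open too, as untested.

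Other splits of the samples were also compared. For each comparison of 3 with 3 arrays the 10 splits are too few for a share under 0.05; in each, 1 of 10, the real one, gave as many genes. Real counts and the highest of the others were 6833 and 1, 6906 and 0, 7703 and 0, and 8072 and 0 between lines at 0, 1, 3 and 5 h. They were 1138 and 0, 5262 and 1, and 6287 and 0 for LPS in the CAT line, and 250 and 38, 1024 and 53, and 959 and 29 in the Tbc1d23 line. Whole slides also allow 10 splits only, of which 1 gave as much: 10671 and 1521 genes for the line difference averaged over times, 364 and 0, 2520 and 0, and 3507 and 0 for the interaction, and sizes of 2.38 and 0.90, 2.98 and 1.08, and 3.64 and 1.39 for the induced sets.

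With lines relabelled within each time compared, 1 of 100 splits gave as many genes for the averaged line difference (10671, highest other 3901). For the sizes of the induced sets it was 1 of 100 each (2.38 and 1.88, 2.98 and 2.47, 3.64 and 3.47). These splits break up slides, whose arrays vary together, and splits of whole slides are too few, so no statement on chance rests on them. At 5 h the mean response of the induced set was 1.12 to 1.40 on the Tbc1d23 slides and 5.20 to 5.36 on the CAT slides. For the number of interaction genes 9, 12 and 8 of 100 splits gave as many at 1, 3 and 5 h (364 and 5678, 2520 and 5960, 3507 and 9064). With labels exchanged within all 4 times, it was 1, 1 and 2 of 100 (highest others 273, 317 and 6978), again with slides broken up. Splits that call several times the real count point to a structure of the samples: those with the most genes mixed the lines unequally at the 2 times compared, which turns the line difference into an apparent difference in response, so they do not measure chance.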

How the results depend on the processing

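The slide run as a block, the slides of 1 run alone and the repaired normexp fit were chosen after seeing the data; the other alternatives were planned. Counts of genes stayed within 1.5 times the main value in 524 cases and moved further in 64. By the direction and call of the list test, lists stayed the same in 5097 cases, lost their call in 189 and reversed in 2. List medians changed sign in more cases with the direction of the test kept, such as negative regulators for the interaction at 1 h under median scaling (-0.36 to 0.07, where the median of all genes moved by 0.42) and antigen presentation there under quantile normalization (-0.11 to 0.08, where it moved by 0.07). Named genes stayed the same in 4086 cases, lost the call in 15 and gained it in 11. The medians of the induced sets kept their direction in all 129. Where a cause is not given below, the cause was not tested.

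Median scaling called 3061, 4180 and 4702 genes between lines at 1, 3 and 5 h, 419, 2356 and 3203 for LPS in the CAT line, 147, 481 and 222 in the Tbc1d23 line, and 70, 1108 and 1348 for the interaction. Array medians (9.7 to 44.9 signal units) lie near background, where the scaling is least certain.

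Normexp as planned called 1132, 1578, 1813 and 978 genes between lines and 4471 on average, 199, 1161 and 1438 for LPS in the CAT line, 33, 87 and 19 in the Tbc1d23 line, and 43, 165 and 225 for the interaction. It reversed oxidative phosphorylation at 0 h (0.20) and pattern recognition receptors for the interaction at 1 h (0.47). Its fit failed on 6 of 24 arrays with 2 to 20 spots over 100 units below background, whose 5th percentile became 213 to 1180 against 57.3 to 61.6 on the others. Leaving those spots out of the fit gave 57.3 to 69.1 and kept every count within 1.5 times. As planned, normexp also ended the interaction calls of Txnip, Rgs2, Zkscan14, Zfp30 and Ifit1 at 1 h, Klhl24 and Slc26a11 at 3 h and Ranbp3l, Fam131a and Neurl3 at 5 h; the repaired fit ended that of Zfp30 alone among these. Of the interaction lists planned normexp ended cytokines (adjusted p = 0.643), chemokines (0.0741), interferon-stimulated genes (0.46), inflammatory mediators (0.223) and antigen presentation (0.681) at 1 h, T and NK markers at 3 and 5 h (0.85 and 0.873), and cell cycle (0.0967) and the Rab TBC family (0.0778) at 5 h. Between lines it ended interferon-stimulated genes (0.38), inflammatory mediators (0.357) and lipid handling (0.0614) at 0 h, and cytokines (0.119), chemokines (0.147), the unfolded protein response (0.119), pattern recognition receptors (0.0649) and heat shock and p53 stress (0.118) at 1 h. It ended oxidative phosphorylation at 3 h (0.286) and cell cycle at 5 h (0.0542) between lines and T and NK markers for LPS in the CAT line at 3 h (0.401).

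No filter on dim probes called 10483 genes between lines at 0 h and 1372, 1653 and 1977 for LPS in the Tbc1d23 line, all with the Tbc1d23 0 h arrays. The filter on all arrays called 140 for LPS in that line at 1 h, and every probe separately 1710 and 379 for the CAT and Tbc1d23 lines at 1 h.

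The replicate block within a line (arrays paired through their slide) called 2645 genes for LPS in the CAT line at 1 h, 702, 2526 and 2351 in the Tbc1d23 line and 880, 4581 and 6002 for the interaction; it takes the differences between slides out of the spread. Of the lists it ended calls of T and NK markers for LPS in the CAT line at 3 h (adjusted p = 0.0614) and for the interaction at 3 h, and those of interferon-stimulated genes, cholesterol synthesis and glycolysis for the interaction at 1 h. A block shared by number across the lines, which the correlations do not bear out, ended oxidative phosphorylation at 0 h (adjusted p = 0.0567), the same 3 lists at 1 h and negative regulators between lines at 5 h (adjusted p = 0.0617).

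Fitting only the groups compared called 72, 321 and 205 genes for LPS in the Tbc1d23 line, whose arrays varied more (lowest r 0.967, CAT 0.981). A 2-fold minimum, which can only lower a count, gave 2782, 2886, 3703 and 4085 between lines, 3484 on average, 514, 2288 and 2916 for LPS in the CAT line, 419 and 316 in the Tbc1d23 line at 3 and 5 h, and 1437 and 2005 for the interaction at 3 and 5 h.

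The slide run as a block called 1738 genes for LPS in the CAT line at 1 h, 385, 1621 and 1556 in the Tbc1d23 line and 553 for the interaction at 1 h. The slides of 1 run called 460 and 363 in the Tbc1d23 line at 3 and 5 h and 238 and 1646 for the interaction at 1 and 3 h, with 1 Tbc1d23 array per time and the spread from CAT arrays alone.

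Without single arrays no count moved by more than 1.5 times. Ranges were 5892 to 6970, 5854 to 7074, 6761 to 7846 and 7214 to 8202 between lines, 10445 to 10792 on average, 916 to 1169, 4622 to 5375 and 5592 to 6379 for the CAT line, 184 to 337, 733 to 1089 and 678 to 1000 for the Tbc1d23 line and 291 to 377, 2166 to 2609 and 3075 to 3610 for the interaction. Set medians ranged from -2.43 to -2.22, -3.03 to -2.85 and -3.75 to -3.45. With set minimums of 1 and 3 they were -1.91, -2.08 and -2.36, and -2.39, -3.09 and -4.94.

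Signal over background limits the results for dim genes: 12.5 to 42.1% of processed signals per array were surrogates, so their folds are bounds. Both extremes were Tbc1d23 arrays at 0 h, replicates 1 and 2.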

Other observations

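The tests in this part were all chosen only after the result was seen.

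Hypothesis: genes induced at 1 h lose more of their response by 5 h in the Tbc1d23 line. Over the 88 genes of the 1 h set the median of the 5 h minus the 1 h difference in response was -0.83. The mean response per slide went from 2.57 to 1.77 in the Tbc1d23 line, a change of -0.80 ± 0.11, and from 5.07 to 5.02 in the CAT line, a change of -0.04 ± 0.06 (SD, n = 3 slides). The test went with the hypothesis.

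Hypothesis: lower transcripts of the LPS receptor genes Tlr4, Cd14 and Ly96 together precede the smaller response. Of the 3, 0 were called lower in the Tbc1d23 line at 0 h. Tlr4 was not called (-0.28 ± 0.22, limma adjusted p = 0.331), and Cd14 (0.87 ± 0.12, adjusted p = 1.45e-05) and Ly96 (0.75 ± 0.10, adjusted p = 6.66e-06) were higher. The test went against the hypothesis; receptor protein was not analysed here.

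Hypothesis: less Ifnb1 transcript accompanies the smaller response of interferon-stimulated genes. At 3 h of LPS, where Ifnb1 was above background in both lines, it was lower in the Tbc1d23 line (log2 -5.11). At 0 h it was not above background in either line, so no difference in response is given. The test went with the hypothesis, as most induced genes would, so it shows no link to those genes.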
